A study of Homo sapiens with 54 samples.

How the data were processed

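RNA was sequenced from human monocyte-derived dendritic cells (moDCs), antigen-presenting cells grown in culture from blood monocytes. Per the labels' protocols, monocytes were cultured for 3 days with GM-CSF (100 ng/mL) and IL-4 (100 ng/mL), given AB598, an antibody against the ATP-degrading ectoenzyme CD39, or an isotype control antibody (each 100 nM) for 1 h, and then kept for 3 more days with or without ATP (300 µM), docetaxel (0.1 µM), a drug that stabilises microtubules, and A549 cells, a human lung adenocarcinoma line. Viable moDCs were then separated from A549 cells by positive selection for CD11c, per the labels. Libraries were made from polyadenylated RNA with a kit that keeps strand information, per the labels. The 54 libraries came from 6 donors, each of whom gave 1 library to each of 9 groups, so every group had n = 6 donors.

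The deposited values were estimated counts per gene (expected counts, as salmon gives them), in 1 table with 60664 gene entries and no normalization. Per the submitters' processing notes the tools were Trim Galore, STAR and Salmon with the GRCh38 build. Their versions, the annotation release and the strand setting are not given in the sources used here. Of the values, 14.0% were not whole numbers (any remainder after division by 1), and all were rounded before testing. Gene names came from a table of gene identifiers and symbols that matched 99.7% of the entries, and gene positions from a GENCODE annotation of GRCh38. Salmon divides reads between similar transcripts by estimation, so values of genes with near-identical copies (tubulins, HLA genes, mitochondrial genes with nuclear copies, pseudogenes such as VNN3P, SNX18P8, GXYLT1P3 and OTOAP1) are uncertain, and so are those of genes with an antisense partner such as TUBA1B.

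Differences were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Normalization factors were computed by TMM, genes with low counts were removed with filterByExpr, which left 17442 genes, and 1 quasi-likelihood model with a term for each group and each donor was fitted to all 54 libraries (40 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene below is from this fit unless another is named. Levels are CPM, counts scaled to library size, computed from the deposited counts with the TMM factors, given as mean ± SD over 6 donors, and log2 fold changes carry the standard error (SE) of the fit. The donor labels pair the libraries across groups. Deviations from the group means correlated within donors (median r 0.398 over pairs of libraries of a donor, lowest 0.105) and not between donors (median -0.0999), and 53 of the 54 libraries correlated best with another library of their own donor. Donors are separate people, so p-values refer to how effects vary over them. No 2 libraries held identical values, and the highest correlation between 2 libraries was 0.991.

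There were 8 comparisons, each within a background that the other treatments hold constant: AB598 against isotype control in 3 backgrounds (moDCs alone, with docetaxel, with docetaxel and A549 cells), ATP against no ATP in the same 3 backgrounds, docetaxel against none, and A549 cells against none in the presence of docetaxel. Every group with ATP also had AB598, so the effect of ATP was measured only with CD39 inhibited. Whether an effect differed between backgrounds was tested with 4 interaction contrasts. Expression of 34 gene lists (636 symbols, of which 1 was not found) covering dendritic cell states, antigen presentation, inflammatory, purinergic, metabolic and stress pathways, and markers of A549 and of other blood cells was tested with camera at a preset correlation between genes of 0.01. For 33 lists at least 5 members were measured, and their p-values were adjusted within each comparison. Because members of a list can vary together, camera was also run with the correlation estimated from the data. Genes raised or lowered at least 2-fold by ATP (called, absolute log2 fold change of at least 1) formed 2 further sets, the ATP signature, tested in AB598 comparisons that share no library with the ATP comparison the set came from. Mean log2 CPM over the A549 and epithelial markers (prior count 2) was compared with exact two-sided sign-flip permutation tests over the 6 donor pairs, whose smallest possible p is 0.03125.

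Named genes were chosen by a rule. A gene had to be called, change in the same direction in all 6 donors, reach 1 CPM in the higher group and have a symbol that is not a clone name. Those with the largest fold changes were taken, 10 in each direction for ATP alone, AB598 with docetaxel and A549, docetaxel, and A549, and 4 in each direction for the other comparisons and the interactions. For A549 cells 10 in each direction were also taken among genes with at least 10 CPM in moDCs with docetaxel and without A549 cells. Up to 4 called members with the smallest p were added for each list that was called or had 3 called members, and 16 genes were reported in every comparison whatever their values. The groups, comparisons, tests, lists and this rule were chosen before the data were examined. X-inactivation and Y-linked genes are not reported here (19 genes). Some other genes that the rule selected are not reported here either. A fold against a group with no count is given as a lower bound from 3 counts over the group, and one against 1 to 3 counts as a ratio with a 95% exact Poisson interval. Such intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

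Alternatives were a model without the donor term, size factors by RLE in place of TMM, no filter on low counts, DESeq2 1.42.0, models of the compared groups only, the A549 marker level as a covariate in the co-culture, each donor left out in turn, an estimated correlation for the lists, and a prior count of 0.5 for levels. Chosen after seeing the data were fits to donors 1 to 3 only and to donors 4 to 6 only, sets of 3 that separated on the level of CD14 and are not groups of the study, and fits with the deepest library thinned or left out. Changed genes added to simulated counts were recovered in the comparison of AB598 alone in 8% of 50 genes at 1.25-fold, 42% at 1.5-fold, 70% at 2-fold and 88% at 4-fold (17151 genes). The shares were 10%, 50%, 74% and 92% for AB598 with docetaxel and A549 (17106 genes), 12%, 46%, 54% and 88% for docetaxel (17160 genes), and 16%, 58%, 72% and 98% for ATP alone (17110 genes). Of the calls in these simulations 2.80%, 9.60%, 1.96% and 4.69% were genes that had not been changed.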

Results

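Transcript levels were measured in moDCs of 6 donors under 9 conditions. The 3 antibody and ATP treatments were isotype control, AB598, and AB598 with ATP. Each was given in 3 backgrounds, namely moDCs alone, moDCs with docetaxel, and moDCs with docetaxel and A549 cells, here called the co-culture. Counts of 39439 genes were above 0 in at least 1 library. The total count per library lay between 13603000 and 20903000 in 53 libraries. Replicate 5 of the isotype group held 184180000 counts, 10.9 times the median of the others. Transcripts of A549 and epithelial markers were low without A549 cells and remained in the co-culture libraries after CD11c selection. KRT8, a keratin of simple epithelia, was at 396 ± 218 CPM in the co-culture with isotype control, 579 ± 402 with AB598 and 975 ± 674 with AB598 and ATP (mean ± SD, n = 6 donors). With docetaxel and no A549 cells it was at 0.0782 ± 0.135 CPM. The mean log2 CPM of the markers was 5.37 ± 0.884 higher with A549 cells than without (6 of 6 donors, exact sign-flip p = 0.03125, the smallest this design allows). Within the co-culture it was higher by 0.39 ± 0.488 with AB598 (4 of 6 donors, exact p = 0.125). ATP raised it by a further 0.64 ± 0.369 (6 of 6 donors, exact p = 0.03125, and exact p = 0.359 without pairing the donors). The share of counts from mitochondrially encoded genes was 4.82 ± 1.31% with isotype control, 5.0 ± 1.38% with AB598 and 6.17 ± 0.822% with AB598 and ATP in moDCs alone. In the co-culture the shares were 5.0 ± 1.55%, 5.5 ± 1.05% and 7.48 ± 1.10%.

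**Figure D1:**
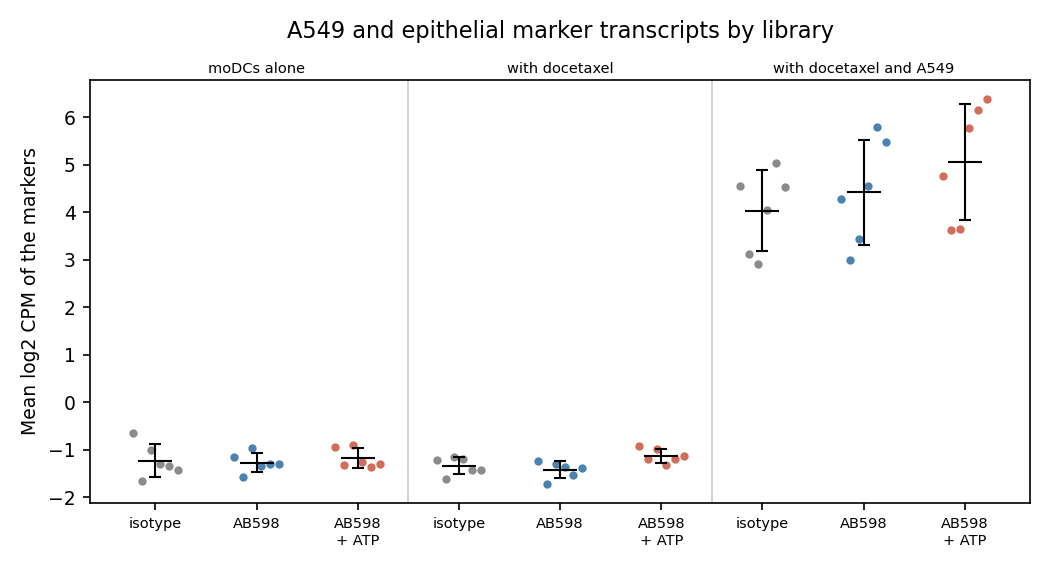
Mean log2 CPM of the A549 and epithelial marker transcripts (y axis) in each of the 54 libraries, by group (x axis), with 1 point per donor, a bar at the group mean and error bars of 1 SD (n = 6). Groups with A549 cells lie 5.37 ± 0.884 log2 units above those without for isotype control, and the highest mean is in the co-culture with AB598 and ATP (5.06).

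ENTPD1, the gene of CD39 (GRCh38 chromosome 10, 95711779 to 95869695, plus strand; ENSG00000138185), was measured in every group. In moDCs alone it was at 59.8 ± 22.8 CPM with isotype control, 69.2 ± 25.5 with AB598 and 166 ± 75.0 with AB598 and ATP. With docetaxel the levels were 60.4 ± 29.6, 65.1 ± 26.0 and 165 ± 77.8 CPM. In the co-culture they were 69.7 ± 45.2, 128 ± 79.5 and 165 ± 127 CPM. ATP raised the transcript in moDCs alone (log2 fold change 1.18 ± 0.25 SE, adjusted p = 0.00017) and with docetaxel (log2 fold change 1.30 ± 0.25 SE, adjusted p = 4.5e-05). The difference with ATP in the co-culture was 0.21 ± 0.24 (adjusted p = 0.54). AB598 raised it in the co-culture (log2 fold change 0.87 ± 0.25 SE, adjusted p = 0.034, higher in 6 of 6 donors). That call was lost without replicate 1 (0.91), 2 (0.95), 3 (0.73), 4 (0.91) or 6 (0.74), each value the log2 fold change. It was also lost without the donor block (0.88), without the low-count filter (0.85) and with the A549 marker level as a covariate (0.65). The differences with AB598 were 0.21 in moDCs alone and 0.15 with docetaxel (adjusted p = 1 in both). The antibody binds the protein, so the transcript does not check the treatment.

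The first comparison asked what ATP does to moDCs whose CD39 is inhibited. Transcripts of mature dendritic cells were higher with ATP in moDCs alone. CCR7, the chemokine receptor that guides dendritic cells to lymph nodes, was 26.4-fold higher (262 ± 149 against 9.32 ± 3.30 CPM; log2 fold change 4.72 ± 0.43 SE, adjusted p = 1.4e-11). The gene lies on GRCh38 chromosome 17, 40553769 to 40565472, minus strand. The costimulatory genes CD80, CD86 and CD40 rose by log2 fold changes of 1.87 ± 0.20, 1.03 ± 0.15 and 1.09 ± 0.22, each in 6 of 6 donors. CD83 rose by 1.15 ± 0.26 in 5 of 6. IL12B, which encodes the shared subunit of IL-12 and IL-23, rose by 6.13 ± 0.72 (18.4 ± 14.6 against 0.424 ± 0.690 CPM). The actin-bundling gene FSCN1 rose by 3.74 ± 0.32, MARCKSL1 by 3.92 ± 0.32, TRAF1 by 3.18 ± 0.29 and TNFRSF9 by 5.77 ± 0.46. The dendritic cell maturation and costimulation list had 29 of 30 members higher and 0 lower (29 and 0 adjusted over the list alone). The median was 2.71 (log2 fold, adjusted p = 3.0e-26, adjusted p = 0.05024 with an estimated correlation).

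Other immune genes moved in both directions. IDO1, which starts the breakdown of tryptophan, rose by 6.76 ± 0.79 and the IL-2 receptor gene IL2RA by 5.88 ± 0.74. IL4I1 and TNFRSF1B rose by 2.49 ± 0.26 and 2.18 ± 0.18. The immune regulation list had 10 of 21 members higher and 3 lower (11 and 3 adjusted over the list alone). The median was 0.46 (log2 fold, adjusted p = 0.031, adjusted p = 0.93 with an estimated correlation). Of the moDC identity list, the transcription factor gene IRF4 and the chemokine genes CCL17 and CCL22 rose by 2.49 ± 0.24, 2.77 ± 0.32 and 2.96 ± 0.39. The lectin gene CD209 fell by 1.44. The complement genes C1QA, C1QB and C1QC had log2 fold changes of -1.65, -1.68 and -1.66, and MAF one of -1.08. The monocyte and macrophage list had 2 of 23 members higher and 14 lower (2 and 15 adjusted over the list alone). The median was -1.65 (log2 fold, adjusted p = 0.026, adjusted p = 1 with an estimated correlation). IL6 (-3.60 ± 0.88, adjusted p = 0.00091) fell in donors 4 to 6 but was at most 0.502 CPM in donors 1 to 3. TNF (-1.30 ± 0.46, adjusted p = 0.02) was lower in 5 of 6 donors. IL1B was at -0.43, adjusted p = 0.53.

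Purinergic genes changed individually. The ATP-gated channel gene P2RX7 fell to 4.36 ± 3.31 against 24.0 ± 11.2 CPM (log2 fold change -2.58 ± 0.28 SE, adjusted p = 5.5e-10). P2RY11 and P2RY12 had log2 fold changes of -1.15 ± 0.22 and -5.03 ± 0.78. The adenosine receptor gene ADORA2A rose by 3.60 ± 0.60, and NT5E, which encodes the AMP-hydrolysing enzyme CD73, by 5.77 ± 0.87. P2RY8 rose by 2.71 ± 0.33 and P2RY10 by 3.47 ± 0.52. ADORA2B was at -0.23, adjusted p = 0.61, and P2RX4 at 0.03, adjusted p = 0.93. Nuclear genes of oxidative phosphorylation, such as COX5B (-0.76) and UQCRC2 (-0.64), had 0 of 22 members higher and 21 lower (0 and 21 adjusted over the list alone). The median was -0.48 (log2 fold, adjusted p = 9.2e-09, adjusted p = 0.32 with an estimated correlation). The mitochondrially encoded genes, such as MT-CO1 (0.54), had 11 of 13 members higher and 0 lower (11 and 0 adjusted over the list alone). The median was 0.38 (log2 fold, adjusted p = 0.012, adjusted p = 1 with an estimated correlation). Other called members of lists that rose were the matrix genes MMP10 (6.85 ± 0.64) and THBS1 (5.19 ± 0.79), the receptor tyrosine kinase gene AXL (5.06 ± 0.66), the thioredoxin gene TXN (2.11 ± 0.22) and the chemokine gene CXCL16 (1.92 ± 0.22). Those that fell were the lipoprotein lipase gene LPL (-2.63 ± 0.38), the scavenger receptor gene CD36 (-1.72 ± 0.30) and CASP1 (-1.24 ± 0.21).

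The largest increases were in genes at or near 0 without ATP. PTPRN, a gene of secretory granule membranes (chromosome 2, 219289623 to 219309648, minus strand), had no count in 6 AB598 libraries and was at least 2513-fold higher. CRHR1, C1QTNF1, GNG4 and the pseudogene VNN3P also had no count and were at least 127-fold, 111-fold, 91.6-fold and 72.3-fold higher. SLC6A3 was higher by 4429-fold (95% counting interval 795 to 174990.0, from 1 control count). MEG3 was higher by 401-fold (95% counting interval 137 to 1946, from 3 control counts) and CALCA by 284-fold (95% counting interval 96.9 to 1379.9, from 3 control counts). NPTX1 and RASD2 had log2 fold changes of 9.18 ± 1.23 and 8.68 ± 0.96. The largest decreases were in IL22RA2 (-5.5 ± 0.59), P2RY12, CCDC85A (-4.48 ± 0.64), ROR2 (-4.17 ± 0.70), and TMEM130 (-4.05 ± 0.42). Next came the sodium channel gene SCN9A (-3.95 ± 0.48), CMBL (-3.94 ± 0.60), the pseudogenes SNX18P8 (-3.74 ± 1.26) and GXYLT1P3 (-3.66 ± 0.55), and ADAM23 (-3.60 ± 0.50).

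In all, edgeR called 7379 of 17442 genes with ATP in moDCs alone, 3780 higher and 3599 lower, and 1788 and 1022 of these differed at least 2-fold. Without the donor block 4690 genes were called. Of 33 lists 5 were called at the preset correlation, 0 of them with an estimated correlation.

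With docetaxel present, ATP again raised genes of dendritic cell maturation. CCR7 was at 213 ± 116 against 6.47 ± 1.67 CPM (log2 fold change 5.02 ± 0.44 SE, adjusted p = 7.7e-12). CD80, CD86 and CD40 rose by 1.73 ± 0.20, 1.00 ± 0.15 and 1.20 ± 0.22, and IL12B by 6.31 ± 0.78. The dendritic cell maturation list had 29 of 30 members higher and 0 lower (29 and 0 adjusted over the list alone). The median was 2.81 (log2 fold, adjusted p = 5.6e-28, adjusted p = 0.035 with an estimated correlation). PTPRN and SLC6A3 had no count without ATP and were at least 2174-fold and 1214-fold higher. NPTX1 was higher by 1692-fold (95% counting interval 468 to 13981, from 2 control counts), and RASD2 rose by 9.89 ± 1.00. P2RY12, P2RY13, GPR143 and ROR2 had the largest decreases (log2 fold changes -5.15, -4.82, -4.13 and -3.90). P2RX7 was at -2.05 ± 0.27.

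Nuclear oxidative phosphorylation genes had 0 of 22 members higher and 19 lower (0 and 20 adjusted over the list alone). The median was -0.44 (log2 fold, adjusted p = 1.4e-08, adjusted p = 0.33 with an estimated correlation). Mitochondrially encoded genes had 13 of 13 members higher and 0 lower (13 and 0 adjusted over the list alone). The median was 0.54 (log2 fold, adjusted p = 2.5e-05, adjusted p = 0.72 with an estimated correlation). The glucose transporter gene SLC2A1 rose by 2.24 ± 0.26 and the lactate dehydrogenase gene LDHA by 0.75 ± 0.14. The hypoxia and glycolysis list had 8 of 22 members higher and 1 lower (8 and 1 adjusted over the list alone). The median was 0.30 (log2 fold, adjusted p = 0.039, adjusted p = 0.72 with an estimated correlation). The monocyte and macrophage list, with C1QB at -1.46 and MERTK, a receptor for apoptotic cells, at 2.03, had 2 of 23 members higher and 13 lower (2 and 14 adjusted over the list alone). The median was -1.38 (log2 fold, adjusted p = 0.038, adjusted p = 0.94 with an estimated correlation). For immune regulation the list had 9 of 21 members higher and 4 lower (9 and 4 adjusted over the list alone). The median was 0.28 (log2 fold, adjusted p = 0.039, adjusted p = 0.72 with an estimated correlation). The T and NK cell list had 4 of 8 members higher and 0 lower (4 and 0 adjusted over the list alone). The median was 1.89 (log2 fold, adjusted p = 0.026, adjusted p = 0.2 with an estimated correlation). Its called members were CD8A (6.46 ± 0.59), IL32 (3.59 ± 0.42), CD5 (2.25 ± 0.45) and KLRD1 (2.89 ± 0.83).

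A total of 7129 genes were called with ATP in the presence of docetaxel (3580 higher and 3549 lower, of which 1738 and 954 at least 2-fold). The count was 4369 without the donor block and 4463 in donors 1 to 3 only. Of the calls, 3040 were higher and 2962 lower in both this comparison and that in moDCs alone, against 776 and 732 if the calls were independent. Fold changes of the 2 comparisons, which share no library, correlated across genes (r = 0.864, Spearman's rho = 0.855; genes are not independent replicates). For the interaction of ATP with docetaxel edgeR called 0 genes (275 at an unadjusted p under 0.05). DESeq2 called 3, MKKS, F8A2 and 7SK, named after their values were seen.

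**Figure D2:**
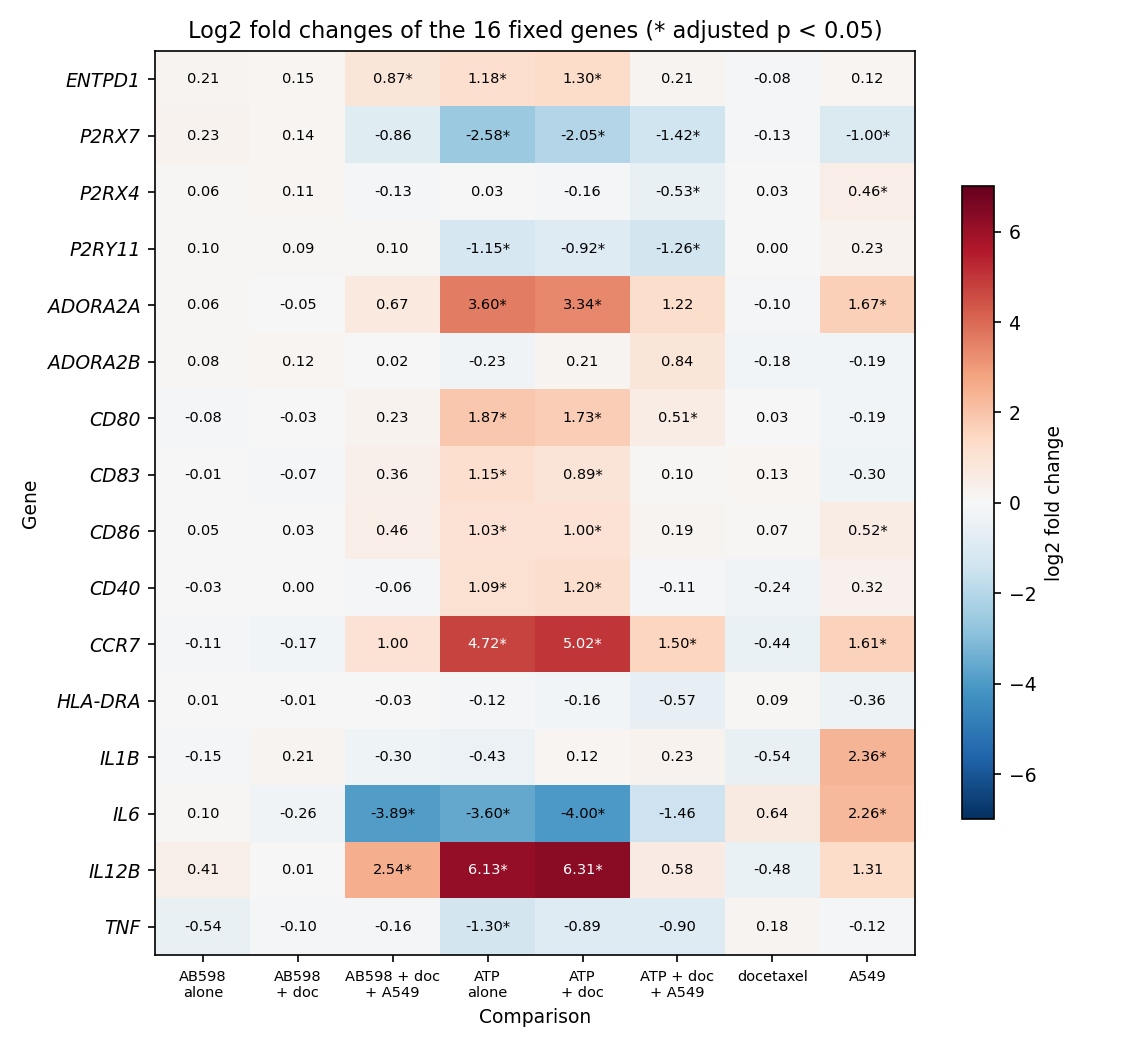
Log2 fold changes of the 16 genes reported in every comparison (rows are genes, columns the 8 comparisons, colour the log2 fold change, asterisks an adjusted p under 0.05, n = 6 donors per group). CCR7 is at 4.72 and 5.02 with ATP without A549 cells and at 1.5 with ATP in the co-culture, and only ENTPD1, IL6 and IL12B carry an asterisk with AB598 in the co-culture.

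Docetaxel was compared with no drug in moDCs with isotype control. The beta-tubulin genes TUBB and TUBB4B rose in 6 of 6 donors. TUBB (chromosome 6, 30720201 to 30725426, plus strand) was at 1374 ± 167 against 605 ± 128 CPM (log2 fold change 1.22 ± 0.14 SE, adjusted p = 2.1e-07). TUBB4B (chromosome 9, 137241213 to 137243707, plus strand) was at 302 ± 22.3 against 159.9 ± 25.5 CPM (log2 fold change 0.92 ± 0.09 SE, adjusted p = 1.8e-08). TSC22D3, which encodes a glucocorticoid-induced leucine zipper protein, fell to 10.2 ± 5.07 against 37.1 ± 33.2 CPM (log2 fold change -1.62 ± 0.30 SE, adjusted p = 0.0071). The nuclear lamin gene LMNA fell to 247 ± 49.3 against 467 ± 159.8 CPM (log2 fold change -0.88 ± 0.15 SE, adjusted p = 0.0016). TAGLN2 fell to 83.8 ± 11.2 against 149.9 ± 46.5 CPM (log2 fold change -0.81 ± 0.12 SE, adjusted p = 0.00012). RAB11FIP1 fell to 118 ± 51.9 against 168 ± 56.1 CPM (log2 fold change -0.56 ± 0.11 SE, adjusted p = 0.014). MYADM, chosen after its values were seen because it was the only other call, was at -1.251 ± 0.26 (adjusted p = 0.037). None of the 16 genes reported in every comparison was called (adjusted p = 1 for each). The tubulin list had 2 of 16 members higher and 0 lower (7 and 0 adjusted over the list alone). The median was 0.40 (log2 fold, adjusted p = 6.7e-36, adjusted p = 1.5e-08 with an estimated correlation).

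Other lists were called with no called member. Cholesterol synthesis had 0 of 24 members called (median log2 fold change -0.22, adjusted p = 1.1e-06, adjusted p = 0.72 with an estimated correlation), with a median of -0.21 when 1 gene was set at its bound. Mitochondrially encoded genes had 0 of 13 called (median log2 fold change 0.12, adjusted p = 3.0e-06, adjusted p = 0.72 with an estimated correlation), matrix remodelling 0 of 21 (median log2 fold change -0.23, adjusted p = 0.004, adjusted p = 0.72 with an estimated correlation). Oxidative phosphorylation had 0 of 22 called (median log2 fold change -0.07, adjusted p = 0.006, adjusted p = 0.76 with an estimated correlation). Dendritic cell maturation had 0 of 30 called (median log2 fold change -0.17, adjusted p = 0.012, adjusted p = 0.8 with an estimated correlation). Hypoxia and glycolysis had 0 of 22 called (median log2 fold change -0.07, adjusted p = 0.038, adjusted p = 0.72 with an estimated correlation), and cAMP targets 0 of 24 (median log2 fold change -0.15, adjusted p = 0.044, adjusted p = 0.8 with an estimated correlation). Among 17442 genes 7 were called, 2 higher and 5 lower (336 at an unadjusted p under 0.05). The count was 2 without the donor block (TUBB and TUBB4B), 14 with DESeq2, 11 in a fit of the 2 groups and 3 in donors 1 to 3 only. It was 4 without replicate 4, 4 without replicate 5, which takes out the deepest library, and 3 without replicate 6. TUBB and TUBB4B were among the calls in each of these 3 fits, and TSC22D3 in none (adjusted p = 0.076 without the deepest library alone).

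A549 cells were compared with none in moDCs given docetaxel and isotype control, so RNA of A549 cells left after selection is part of this difference. The fibrinogen genes FGA, FGG and FGB had no count in 6 libraries without A549 cells and were at least 2612-fold, 1434-fold and 895-fold higher. CLDN2, CNTN1 and CST1 were at least 892-fold, 901-fold and 904-fold higher. KRT7 was higher by 8399.7-fold (95% counting interval 1507 to 331810.0, from 1 control count). AKR1B10 was higher by 5289-fold (95% counting interval 1809.5 to 25650.0, from 3 control counts) and KRT81 by 5121-fold (95% counting interval 1417 to 42288, from 2 control counts). KRT8 had a log2 fold change of 12.12 ± 0.49. The A549 and epithelial list had 24 of 28 members higher and 2 lower (24 and 2 adjusted over the list alone). The median was 7.18 (log2 fold, adjusted p = 2.3e-49, adjusted p = 1.6e-05 with an estimated correlation). With the 7 members without a count at their bound the median was 6.74.

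Among genes with at least 10 CPM in moDCs without A549 cells, the transglutaminase gene TGM2 (chromosome 20, 38127387 to 38166578, minus strand) rose. It was at 15171 ± 3236 against 605 ± 620.1 CPM (log2 fold change 5.21 ± 0.55 SE, adjusted p = 3.4e-10). The chemokine genes CCL24, CCL26 and CCL2 were at 3820.1 ± 1464 against 791 ± 1338 CPM, 539.6 ± 138 against 158 ± 253 CPM and 467 ± 204 against 55.2 ± 56.9 CPM. The control SD was above the control mean for TGM2 and these 3 genes, and their fitted log2 fold changes exceeded the ratio of the means. CCL24, CCL26 and CCL2 rose by 5.46 ± 1.17, 4.18 ± 0.85 and 4.0 ± 0.58 as fitted. Their mean log2 differences over donors were 5.15 ± 3.55, 3.71 ± 2.65 and 3.68 ± 1.44 (SD, n = 6), higher in 6 of 6 donors each. The matrix genes THBS1 and TIMP1 rose by 4.77 ± 0.77 and 4.28 ± 0.49. CHST15, CD300A, ITGA9 and IL17RB rose by 4.63 ± 0.55, 4.59 ± 0.64, 4.52 ± 0.84 and 4.26 ± 0.64. CD1A (chromosome 1, 158254137 to 158258269, plus strand), which presents lipid antigens, fell to 48 ± 76.7 against 509 ± 457 CPM (log2 fold change -3.68 ± 0.29 SE, adjusted p = 5.7e-14). CD1E, the IgE receptor gene FCER1A and the aquaporin gene AQP3 had log2 fold changes of -3.35 ± 0.37, -3.44 ± 0.35 and -3.45 ± 0.45. Those of PTGER3, ARHGEF15, DHRS2, SCN9A, IPCEF1 and MYORG were -6.16, -4.57, -4.46, -3.97, -3.46 and -3.45.

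Gene lists of other cell states moved with the A549 markers, whose mean log2 CPM was 5.37 higher. The monocyte and macrophage list, with S100A9 at 3.66 ± 0.34 and VCAN at 2.32 ± 0.31, had 17 of 23 members higher and 0 lower (18 and 0 adjusted over the list alone). The median was 2.22 (log2 fold, adjusted p = 4.8e-05, adjusted p = 0.44 with an estimated correlation). The moDC identity list had 4 of 24 members higher and 8 lower (5 and 9 adjusted over the list alone). The median was -0.37 (log2 fold, adjusted p = 0.011, adjusted p = 0.61 with an estimated correlation). Interferon-stimulated genes, among them IFIT2 (2.40 ± 0.33), IFIT3 (2.17 ± 0.31) and ISG15 (2.15 ± 0.35), had 26 of 30 members higher and 0 lower (27 and 0 adjusted over the list alone). The median was 1.44 (log2 fold, adjusted p = 1.9e-08, adjusted p = 0.44 with an estimated correlation). The cell cycle list, whose members proliferating A549 cells also express, had 24 of 24 members higher and 0 lower (24 and 0 adjusted over the list alone). The median was 2.96 (log2 fold, adjusted p = 4.9e-12, adjusted p = 0.21 with an estimated correlation). TOP2A of that list was at 4.08 ± 0.39 and TPX2 at 3.65 ± 0.33.

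Immune regulation genes had 16 of 21 members higher and 0 lower (16 and 0 adjusted over the list alone). The median was 1.41 (log2 fold, adjusted p = 4.8e-05, adjusted p = 0.21 with an estimated correlation). Chemokine genes, with CXCL5 at 6.81 ± 0.59 and CXCL10 at 4.65 ± 0.76, had 13 of 25 members higher and 0 lower (14 and 0 adjusted over the list alone). The median was 1.12 (log2 fold, adjusted p = 0.0053, adjusted p = 0.6 with an estimated correlation). Dendritic cell maturation genes, with CCR7 at 1.61 ± 0.40 in 5 of 6 donors, had 16 of 30 members higher and 0 lower (17 and 0 adjusted over the list alone). The median was 0.75 (log2 fold, adjusted p = 0.011, adjusted p = 0.67 with an estimated correlation). Matrix remodelling genes had 10 of 21 members higher and 1 lower (11 and 1 adjusted over the list alone). The median was 1.27 (log2 fold, adjusted p = 0.011, adjusted p = 0.52 with an estimated correlation). NF-kB targets had 10 of 21 members higher and 0 lower (12 and 0 adjusted over the list alone). The median was 0.70 (log2 fold, adjusted p = 0.019, adjusted p = 0.64 with an estimated correlation).

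Hypoxia and glycolysis genes had 10 of 22 members higher and 0 lower (11 and 0 adjusted over the list alone). The median was 0.53 (log2 fold, adjusted p = 0.0011, adjusted p = 0.31 with an estimated correlation). Integrated stress response genes had 10 of 20 members higher and 2 lower (10 and 2 adjusted over the list alone). The median was 0.67 (log2 fold, adjusted p = 0.011, adjusted p = 0.29 with an estimated correlation). Oxidative phosphorylation genes had 0 of 22 members higher and 7 lower (0 and 7 adjusted over the list alone). The median was -0.14 (log2 fold, adjusted p = 0.019, adjusted p = 0.67 with an estimated correlation). CD86 and P2RX4 rose by 0.52 ± 0.15 and 0.46 ± 0.18, IL1B by 2.36 ± 0.53 (5 of 6 donors) and IL6 by 2.26 ± 0.70 (4 of 6 donors; -0.015 in donors 4 to 6 only). P2RX7 fell by 1.00 (5 of 6 donors). In all 6585 genes were called, 3679 higher and 2906 lower, of which 2369 and 546 at least 2-fold. The count was 3700 without the donor block and 4155 in donors 4 to 6 only. Of 33 lists 13 were called at the preset correlation and 1 with an estimated one.

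**Figure D3:**
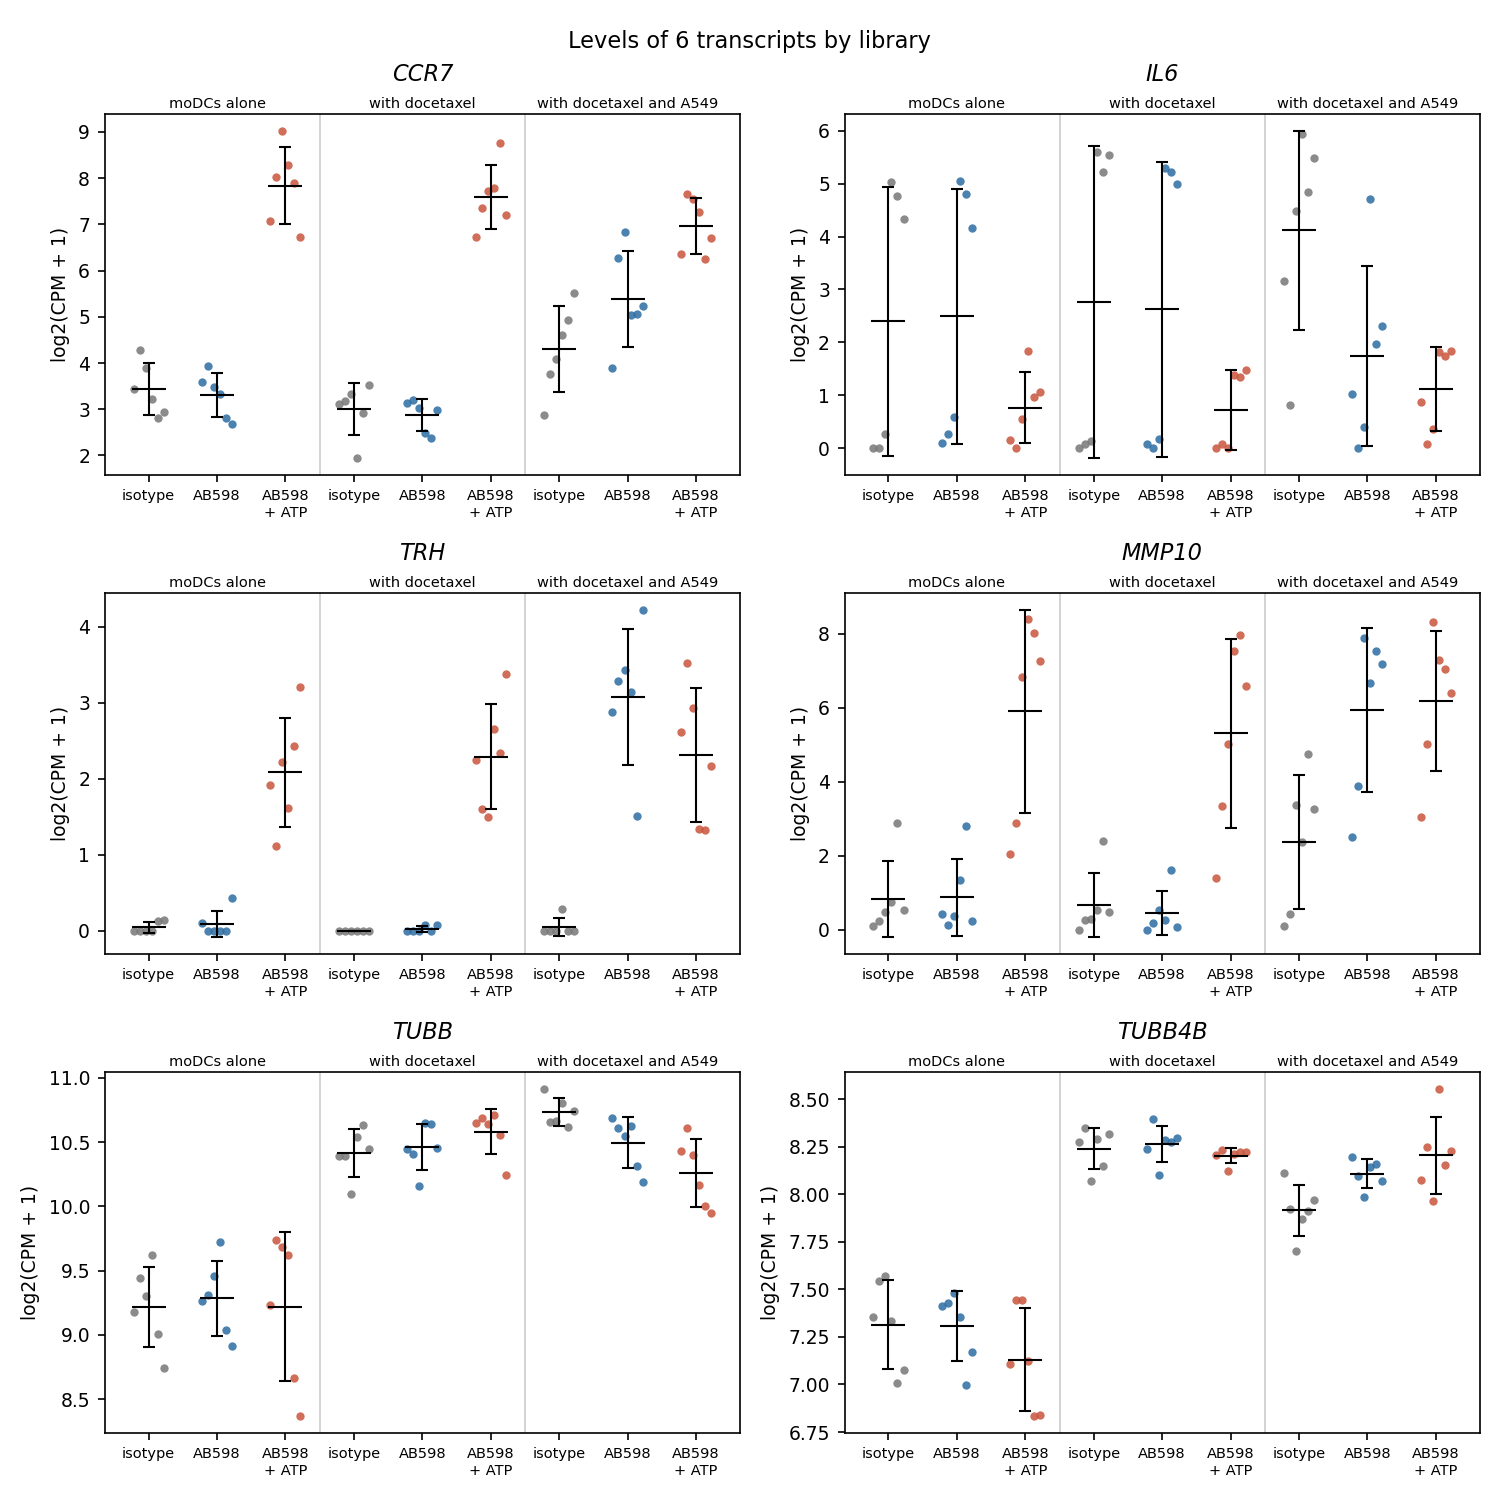
Levels of CCR7, IL6, TRH, MMP10, TUBB and TUBB4B as log2(CPM + 1) (y axes) in each library by group (x axes), with 1 point per donor, a bar at the mean and error bars of 1 SD (n = 6). TUBB was at 605 ± 128 CPM with isotype control and 1374 ± 167 CPM with docetaxel, and CCR7 at 9.32 ± 3.30 CPM with AB598 and 262 ± 149 CPM with AB598 and ATP.

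AB598 was compared with isotype control without added ATP to ask whether CD39 inhibition changes moDCs by itself. In moDCs alone no gene stood out from the spread over donors that the fit pools over all 9 groups. CCR7 was at 9.32 ± 3.30 against 10.5 ± 4.78 CPM (log2 fold change -0.11 ± 0.39 SE, adjusted p = 1). CD86 was at 268 ± 51.3 against 259 ± 57.6 CPM (log2 fold change 0.05 ± 0.15 SE, adjusted p = 1). P2RX7 was at 24.0 ± 11.2 against 20.3 ± 9.32 CPM (log2 fold change 0.23 ± 0.25 SE, adjusted p = 1). edgeR called 0 of 17442 genes (186 at an unadjusted p under 0.05), and DESeq2 called 1 (MKKS). A fit of the 2 groups called 1 (SLC5A3, a myo-inositol transporter gene, at -0.43). Both were named after their values were seen. At the preset correlation 2 lists with 0 called members were called. These were LXR targets (median log2 fold change 0.12, adjusted p = 0.02, adjusted p = 0.99 with an estimated correlation) and mitochondrially encoded genes (median log2 fold change 0.07, adjusted p = 0.019, adjusted p = 0.99 with an estimated correlation).

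With docetaxel, CCR7 was at 6.47 ± 1.67 against 7.43 ± 2.62 CPM (log2 fold change -0.17 ± 0.41 SE, adjusted p = 1). There CD86 was at 276 ± 42.4 against 271 ± 41.5 CPM (log2 fold change 0.03 ± 0.15 SE, adjusted p = 1) and IL6 at 17.6 ± 19.4 against 21.6 ± 23.9 CPM (log2 fold change -0.26 ± 0.63 SE, adjusted p = 1). edgeR again called 0 genes (174 at an unadjusted p under 0.05, again fewer than chance alone would give). DESeq2 called 3 (TLR9 and 2 genes without a symbol), and a fit of the 2 groups 2 (SLC5A3 and THBS1, each at -0.43), named after their values were seen. At the preset correlation 4 lists with 0 called members were called. LXR targets (median log2 fold change 0.14, adjusted p = 0.0046, adjusted p = 0.98 with an estimated correlation) and oxidative phosphorylation (median log2 fold change 0.05, adjusted p = 0.0046, adjusted p = 0.98 with an estimated correlation) were among them. The others were ER stress (median log2 fold change 0.09, adjusted p = 0.04, adjusted p = 0.98 with an estimated correlation) and mitochondrially encoded genes (median log2 fold change -0.08, adjusted p = 0.016, adjusted p = 0.98 with an estimated correlation). For the interaction of AB598 with docetaxel edgeR called 0 genes (155 at an unadjusted p under 0.05) and DESeq2 4 (MKKS, TLR9 and 2 genes without a symbol). In simulated data of AB598 alone, 70% of genes changed 2-fold and 42% of those changed 1.5-fold were recovered.

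In the co-culture, where docetaxel-treated A549 cells were present, AB598 changed many genes. The matrix metalloproteinase gene MMP10 (chromosome 11, 102770503 to 102780628, minus strand) rose to 114 ± 92.3 against 8.08 ± 9.60 CPM (log2 fold change 4.22 ± 0.53 SE, adjusted p = 2.4e-06). CD207, which encodes the Langerhans cell lectin langerin, rose to 13.6 ± 16.3 against 0.704 ± 0.374 CPM (log2 fold change 3.88 ± 0.63 SE, adjusted p = 0.00016). TRH, the gene of the thyrotropin-releasing hormone precursor (chromosome 3, 129974305 to 129977938, plus strand), was higher by 271-fold (95% counting interval 92.5 to 1317, from 3 control counts). PTPRN rose to 4.91 ± 3.58 against 0.0502 ± 0.0782 CPM (log2 fold change 6.74 ± 0.99 SE, adjusted p = 8.6e-05). The cytokine gene IL6 (chromosome 7, 22725884 to 22732002, plus strand) fell to 5.58 ± 9.75 against 27.0 ± 22.4 CPM (log2 fold change -3.89 ± 0.77 SE, adjusted p = 0.0016), lower in 6 of 6 donors. HPGDS, a prostaglandin D synthase gene, fell to 1.16 ± 1.48 against 7.01 ± 6.60 CPM (log2 fold change -2.93 ± 0.51 SE, adjusted p = 0.00041).

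Other increases were in CD8A (4.41 ± 0.65), CYP1A1 (3.87 ± 0.92), SLA2 (3.49 ± 0.56), CLEC4F (3.42 ± 0.63), CACNA2D2 (3.29 ± 0.74) and WNT10B (3.29 ± 0.82). Other decreases were in VXN (-4.56 ± 1.24), the cell cycle transcription factor gene E2F2 (-2.73 ± 0.44), ANOS1 (-2.69 ± 0.58), and the aromatase gene CYP19A1 (-2.41 ± 0.52). Further ones were in PVALB (-2.31 ± 0.55), the pseudogene OTOAP1 (-2.21 ± 0.55) and CLEC12A (-2.14 ± 0.61). IL12B rose by 2.54 ± 0.73 (5 of 6 donors), DPP4 by 0.99 ± 0.26, P2RY6 by 0.76 ± 0.22 and the platelet chemokine gene PPBP by 2.72 ± 0.58. The macrophage receptor gene MARCO and the cholesterol synthesis gene ACAT2 had log2 fold changes of -1.68 ± 0.45 and -0.66 ± 0.20. CCR7 was at 1.00, adjusted p = 0.15, CD86 at 0.46, adjusted p = 0.073 and P2RX7 at -0.86, adjusted p = 0.06, none of them called.

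By lists, dendritic cell maturation had 1 of 30 members higher and 0 lower (10 and 0 adjusted over the list alone). The median was 0.38 (log2 fold, adjusted p = 9.5e-05, adjusted p = 0.77 with an estimated correlation). In donors 4 to 6 only its direction was lower (adjusted p = 0.727). Purinergic genes had 3 of 23 members higher and 0 lower (4 and 5 adjusted over the list alone) (adjusted p = 0.33). Matrix remodelling had 1 of 21 members higher and 0 lower (4 and 0 adjusted over the list alone). The median was 0.29 (log2 fold, adjusted p = 0.012, adjusted p = 0.77 with an estimated correlation). T and NK cell markers had 1 of 8 members higher and 0 lower (2 and 0 adjusted over the list alone). The median was 0.48 (log2 fold, adjusted p = 0.045, adjusted p = 0.4 with an estimated correlation). Platelet markers had 1 of 8 members higher and 0 lower (2 and 0 adjusted over the list alone). The median was 0.40 (log2 fold, adjusted p = 0.045, adjusted p = 0.29 with an estimated correlation). Monocyte and macrophage markers had 0 of 23 members higher and 1 lower (0 and 1 adjusted over the list alone). The median was -0.46 (log2 fold, adjusted p = 0.033, adjusted p = 0.77 with an estimated correlation). Cholesterol synthesis had 0 of 24 members higher and 2 lower (0 and 3 adjusted over the list alone). The median was -0.25 (log2 fold, adjusted p = 0.0069, adjusted p = 0.77 with an estimated correlation).

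Inflammasome genes had 0 of 18 members higher and 0 lower (0 and 0 adjusted over the list alone). The median was -0.29 (log2 fold, adjusted p = 0.034, adjusted p = 0.29 with an estimated correlation). Cell cycle genes had 0 of 24 members higher and 0 lower (0 and 3 adjusted over the list alone). The median was -0.45 (log2 fold, adjusted p = 0.012, adjusted p = 0.77 with an estimated correlation). In donors 4 to 6 only their direction was higher (adjusted p = 0.290). Nuclear oxidative phosphorylation had 0 of 22 members higher and 0 lower (0 and 0 adjusted over the list alone). The median was -0.11 (log2 fold, adjusted p = 0.012, adjusted p = 0.77 with an estimated correlation). A549 and epithelial markers had 0 of 28 members higher and 0 lower (0 and 0 adjusted over the list alone). The median was 0.39 (log2 fold, adjusted p = 0.01, adjusted p = 0.77 with an estimated correlation). Mitochondrial genes had 0 of 13 members higher and 0 lower (0 and 0 adjusted over the list alone). The median was 0.16 (log2 fold, adjusted p = 0.012, adjusted p = 0.77 with an estimated correlation). The A549 marker level had a mean log2 difference of 0.39 ± 0.488 between AB598 and isotype control (higher in 4 of 6 donors, exact p = 0.125). In donors 1 to 3 the differences were -0.28, -0.13 and 0.53 (mean 0.041), and in donors 4 to 6 the mean was 0.74.

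A total of 698 genes were called, 317 higher and 381 lower, of which 128 and 86 at least 2-fold. The count was 49 without the donor block, 408 without the low-count filter, and 1359 in a fit of the 2 groups. It was 236 in that fit of the 2 groups with the A549 marker level as a covariate, 1268 in donors 1 to 3 only and 15 in donors 4 to 6 only. It was 406 without replicate 1, 347 without replicate 2, 147 without replicate 3 and 408 without replicate 6. The effect of AB598 differed from that with docetaxel and no A549 cells in 81 genes by the interaction test (30 higher and 51 lower). Among them were MMP10 (5.01 ± 1.0), CD207 (4.33 ± 0.85), CD8A (5.04 ± 1.22) and CLEC4F (3.83 ± 0.92) on the higher side. On the lower side were HPGDS (-3.28 ± 0.70), E2F2 (-3.24 ± 0.60), OTOAP1 (-3.12 ± 0.77) and CRTAM (-2.26 ± 0.54). That count was 0 without the donor block, without replicate 1 and without replicate 3, 6 without replicate 2 and 7 without replicate 6. It was 35 without the low-count filter, 221 with DESeq2, 229 in donors 1 to 3 and 0 in donors 4 to 6. A fit of the 4 groups called 144, or 299 with the A549 marker covariate.

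The changes with AB598 in the co-culture resembled those with ATP. Of the 1788 genes that ATP raised at least 2-fold in moDCs alone, 83.7% had a positive log2 fold change with AB598 in the co-culture. Over the whole set the median was 0.39 (144 called higher and 0 lower, camera adjusted p = 6.8e-19, adjusted p = 0.0055 with an estimated correlation). Of the 1022 that ATP lowered, 21.9% did. The median of that set was -0.32 (2 called higher and 95 lower, adjusted p = 1.3e-17, adjusted p = 0.012 with an estimated correlation). Per donor the mean log2 differences were 0.43 ± 0.281, above 0 in 6 of 6 donors, and -0.37 ± 0.248, above 0 in 0 of 6 (exact sign-flip p = 0.03125 and adjusted p = 0.047 each). Of the 317 genes called higher and 381 called lower with AB598 in the co-culture, 220 and 282 were called in the same direction with ATP in moDCs alone, against 68.7 and 78.6 if the calls were independent. In the opposite direction 3 of the genes called higher and 10 of those called lower were called. Across all 17442 genes the fold changes of the 2 comparisons, which share no library, correlated with r = 0.439 (rho = 0.406). With docetaxel and no A549 cells the medians of the 2 sets were -0.06 and 0.07 with AB598 (adjusted p = 0.033 and 0.00037, adjusted p = 0.40 and 0.30 with an estimated correlation). With AB598 alone, for the sets taken from ATP with docetaxel (1738 and 954 genes), they were -0.04 and 0.08 (adjusted p = 0.029 and 3.7e-05, adjusted p = 0.40 and 0.29 with an estimated correlation). Per donor the sets that ATP lowered had mean log2 differences of 0.079 ± 0.036 with docetaxel and 0.094 ± 0.073 with AB598 alone. These were above 0, opposite to ATP, in 6 of 6 donors (exact p = 0.03125 and adjusted p = 0.047 each). The sets that ATP raised had -0.036 ± 0.060 and -0.059 ± 0.062, above 0 in 1 of 6 donors (exact p = 0.219 and 0.094, adjusted p = 0.219 and 0.113). Across genes the fold changes correlated with rho = -0.172 between ATP alone and AB598 with docetaxel (r = -0.086). Between ATP with docetaxel and AB598 alone rho was -0.147 (r = -0.044). Neither pair shares a library.

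**Figure D4:**
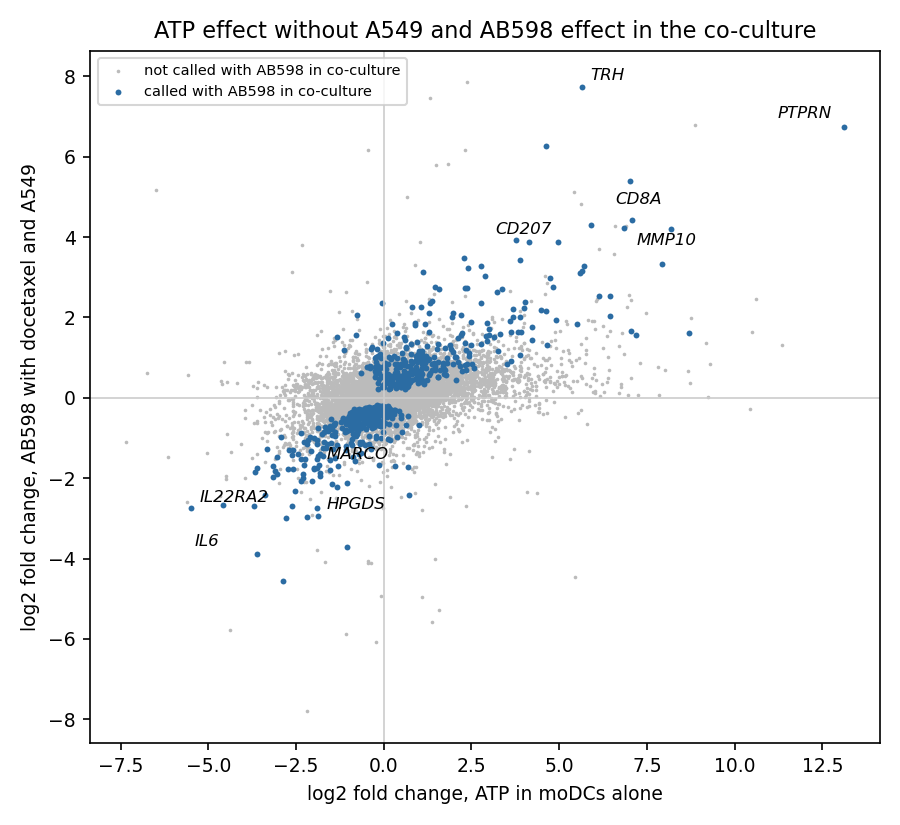
Log2 fold change with ATP in moDCs alone (x axis) against that with AB598 in the co-culture with docetaxel and A549 cells (y axis), 1 point per gene (17442 genes), with the 698 genes called with AB598 in blue. TRH, PTPRN, MMP10 and CD207 lie high on both axes and IL6 low on both, and r is 0.439.

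ATP added to the AB598-treated co-culture raised RASD2 (63.2 ± 60.2 against 0.646 ± 0.509 CPM; log2 fold change 7.43 ± 0.75 SE, adjusted p = 4.4e-09). It also raised SLC6A3 (6.76 ± 0.96), CD300E (5.92 ± 0.95) and WNT1 (5.67 ± 0.88). Genes it lowered were ADRA2B (-3.86 ± 0.59), P2RY14 (-3.73 ± 0.78), P2RY13 (-3.54 ± 0.76) and the hepcidin gene HAMP (2.63 ± 1.82 against 34.0 ± 25.4 CPM; -3.38 ± 0.48). CCR7 rose to 133 ± 54.7 against 50.8 ± 36.9 CPM (log2 fold change 1.5 ± 0.38 SE, adjusted p = 0.0031). CD80 rose by 0.51 ± 0.19 (adjusted p = 0.046), IDO1 by 2.97 ± 0.63 and TNFRSF9 by 1.59 ± 0.36. P2RX7, P2RY11 and P2RX4 had log2 fold changes of -1.42 ± 0.29, -1.26 ± 0.22 and -0.53 ± 0.18. CD86 was at 0.19, adjusted p = 0.35, CD83 at 0.10, adjusted p = 0.81, IL12B at 0.58, adjusted p = 0.46 and IL6 at -1.46, adjusted p = 0.21, none of them called. In donors 4 to 6 only CD86 was at -0.32 and called as lower (adjusted p = 0.021). The dendritic cell maturation list had 14 of 30 members higher and 0 lower (15 and 0 adjusted over the list alone). The median was 0.59 (log2 fold, adjusted p = 0.00042, adjusted p = 0.65 with an estimated correlation).

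Genes of the moDC state were lower. ALOX15, the lectin gene CLEC10A and CD209 had log2 fold changes of -1.71 ± 0.25, -1.90 ± 0.32 and -1.17 ± 0.23. The moDC identity list had 2 of 24 members higher and 12 lower (2 and 13 adjusted over the list alone). The median was -0.60 (log2 fold, adjusted p = 9.3e-05, adjusted p = 0.65 with an estimated correlation). The macrophage lectin gene SIGLEC1 was at -2.28 ± 0.52 and C1QC at -1.48 ± 0.30. Their list of monocyte and macrophage markers had 1 of 23 members higher and 7 lower (1 and 9 adjusted over the list alone). The median was -1.13 (log2 fold, adjusted p = 0.00041, adjusted p = 0.65 with an estimated correlation). Interferon-stimulated genes, including IFI44 (-1.66 ± 0.32) and IFIT3 (-1.5 ± 0.31), had 1 of 30 members higher and 19 lower (1 and 22 adjusted over the list alone). The median was -1.09 (log2 fold, adjusted p = 4.3e-08, adjusted p = 0.65 with an estimated correlation).

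MHC class II genes, with HLA-DMB at -1.04 ± 0.32, had 0 of 14 members higher and 2 lower (0 and 4 adjusted over the list alone). The median was -0.56 (log2 fold, adjusted p = 0.0048, adjusted p = 0.65 with an estimated correlation). MHC class I genes had 1 of 20 members higher and 8 lower (1 and 9 adjusted over the list alone). The median was -0.19 (log2 fold, adjusted p = 0.0022, adjusted p = 0.65 with an estimated correlation). ER stress genes had 2 of 16 members higher and 9 lower (2 and 9 adjusted over the list alone). The median was -0.42 (log2 fold, adjusted p = 0.0048, adjusted p = 0.65 with an estimated correlation). Genes of oxidative phosphorylation had 0 of 22 members higher and 8 lower (0 and 10 adjusted over the list alone). The median was -0.19 (log2 fold, adjusted p = 0.003, adjusted p = 0.65 with an estimated correlation).

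Among lists that were higher, the A549 and epithelial markers had 11 of 28 members higher and 0 lower (14 and 0 adjusted over the list alone). The median was 0.71 (log2 fold, adjusted p = 0.00053, adjusted p = 0.65 with an estimated correlation). The cell cycle list, with MCM5 at 0.98 ± 0.21 and AURKA at 1.04 ± 0.29, had 6 of 24 members higher and 0 lower (9 and 0 adjusted over the list alone). The median was 0.75 (log2 fold, adjusted p = 0.0022, adjusted p = 0.65 with an estimated correlation). Genes of the mitochondrial genome had 10 of 13 members higher and 0 lower (10 and 0 adjusted over the list alone). The median was 0.32 (log2 fold, adjusted p = 0.00056, adjusted p = 0.65 with an estimated correlation). The A549 marker level moved with all of these lists, by 0.64 ± 0.369 in 6 of 6 donors. In all 4204 genes were called, 1883 higher and 2321 lower, of which 558 and 468 at least 2-fold. The count was 1064 without the donor block, 1429 in donors 1 to 3 only and 2375 without replicate 4. A fit of the 2 groups called 5164, or 27 (0 lower) with the A549 marker covariate. With it 15 named genes, AURKA among them (-0.23), changed sign, none of them called.

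The effect of ATP differed from that with docetaxel and no A549 cells in 2121 genes by the interaction test, 831 on the higher and 1290 on the lower side. PDE3A (4.90 ± 1.47), PDZD4 (4.61 ± 1.34), KCNF1 (4.36 ± 1.14) and CMBL (4.36 ± 0.71) had the largest positive differences. PTPRN, TRH, C1QTNF1 and CALCA had the largest negative ones (-9.69, -8.11, -8.06 and -7.77). They were at 0, 0.0187, 0 and 0.0170 CPM with docetaxel and AB598, so these fitted values depend on the prior count. The count was 452 without the donor block, 1375 without the low-count filter, 1306 in a fit of the 4 groups, 924 in donors 1 to 3 only, 1240 without replicate 4 and 1334 without replicate 6.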

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

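Of the tests below, those of genes that moved beyond every A549 marker, of the A549 marker level as a covariate and in each donor, of the ATP-like response and of the starting level that a smaller rise needs were chosen only after the result was seen. Depth was far from the rest in 1 isotype library: the gap to the next library took 0.973 of the range of that group, above Dixon's critical value for 6 samples. The same measure was computed on the paired log2 differences of named genes, where chance flags about 1 in 20 groups of values, and 29 of 649 (4.47%) were above it. With AB598 and docetaxel these were ADORA2A (0.817), CD80 (0.699) and CD86 (0.659). With ATP alone they were TNFRSF9 (0.706), CCL22 (0.646), GP1BA (0.765) and ADORA2A (0.881). With ATP and docetaxel they were NLRC5 (0.766), PYCARD (0.653), TNFRSF1B (0.715), CYP51A1 (0.796), NSDHL (0.6254) and EDEM1 (0.683). With ATP in the co-culture they were TNFSF4 (0.777), PSMB8 (0.777), LPCAT3 (0.676), AURKA (0.697), TPX2 (0.672), ATP5PO (0.649), XBP1 (0.730) and IL6 (0.685). With A549 cells they were MYORG (0.815), CD70 (0.706), DNAJB1 (0.673), TCF4 (0.769), PPBP (0.668), FCGR3B (0.737) and CD86 (0.724), and for the interaction of AB598 with A549 cells OTOAP1 (0.697).

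The effect of AB598 in the co-culture differed from that with docetaxel alone in 81 genes by the interaction test. The named ones were CD8A (5.04, adjusted p = 0.041), MMP10 (5.01, adjusted p = 0.015), CD207 (4.33, adjusted p = 0.013), CLEC4F (3.83, adjusted p = 0.039), HPGDS (-3.28, adjusted p = 0.021), E2F2 (-3.24, adjusted p = 0.0081), OTOAP1 (-3.12, adjusted p = 0.048) and CRTAM (-2.26, adjusted p = 0.039), each in the same direction in 6 of 6 donors. More RNA of A549 cells in the AB598 libraries is a candidate explanation for the 698 genes called there, whether as that RNA itself or as a moDC state that follows its amount. Both are argued against as the whole cause: in the 2 of 6 donors whose A549 marker level was lower with AB598 (log2 differences -0.28 and -0.13), 94.3% and 96.8% of the genes called in the fit without that donor still moved in the called direction. Mean changes in that direction cannot be compared between donors, as each is over another gene set (147 to 637 genes). The largest, 1.55, over 147 genes, was in a donor whose marker level was 0.53 higher. Less decisive was the size of the changes, as 50.9% (355, 95% interval 47.1% to 54.6%) exceeded the A549 marker that rose most (0.65 among 20 markers, mean 0.41), which does not clear the bound of 50% set beforehand, although 29 genes exceeded it in a test against that size, 22 higher and 7 lower. With the marker level as a covariate 18.3% of the called genes (128) were still called and all 659 that could be tested kept their sign. The median absolute log2 fold change went from 0.62 to 0.58 and the median SE from 0.12 to 0.15, so calls were lost mostly to the wider error. A part that follows the amount of A549 RNA stays open, as does a change in which genes A549 cells transcribed. The changes were consistent with an ATP-like response, the hypothesis that the design names: both ATP signatures moved in the direction of ATP in 6 of 6 donors, with a highest adjusted p of 0.012 at an estimated correlation. Because signature and pattern were seen in these data it stays a hypothesis.

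The effect of ATP in the co-culture differed from that with docetaxel alone in 2121 genes. The named ones were PDE3A (4.90, adjusted p = 0.023), PDZD4 (4.61, adjusted p = 0.02), KCNF1 (4.36, adjusted p = 0.0086), CMBL (4.36, adjusted p = 4.6e-05), PTPRN (-9.69, adjusted p = 6.1e-05), TRH (-8.11, adjusted p = 1.3e-06), C1QTNF1 (-8.06, adjusted p = 1.8e-05) and CALCA (-7.77, adjusted p = 6.6e-10), as fitted. The last 4 had 0 to 0.0187 CPM with docetaxel and AB598, so that their fitted values depend on the prior count. A549 transcripts that raise the starting level could hide part of a rise. Of 1078 genes raised less in the co-culture most did start higher there (84.0%, median log2 difference 0.64), but 38.5% (415) started at least 2-fold higher, under the bound of 50% set for excluding it. No start could account for 369 of them, which did not rise in the co-culture as fitted. Of the other 709, 7.90% (56, 95% interval 6.02% to 10.1%) started as high as a fixed added amount would need, which argues against it for the set as a whole. With the level from moDCs lowered to an assumed 50% the share was 18.6% (15.8% to 21.7%), too near the bound of 20% to exclude such a mixture, so that this stays open. If AB598 had already moved the co-culture towards the ATP state, the response counted from isotype control should be about as large with A549 cells as without. Across 2692 genes chosen for their response without A549 cells, for which ATP alone on ATP with docetaxel gave a slope of 0.905, the slope was 0.583 from isotype control (per donor 0.594 ± 0.141, highest 0.774) against 0.339 from AB598, higher in 6 of 6 donors (exact p = 0.03125), and 1278 genes were called for the interaction from isotype control, 848 of them also called from AB598. The rise restates the AB598 shift to the ATP state, so a part from it stays open. A slope under the bound of 0.7 set for excluding it, by less than 1 SD over donors, and below 0.905 in each donor argues against it as the whole cause.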

How the results depend on the processing

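The settings that fit donors 1 to 3 or donors 4 to 6 only and those that thin or leave out the deepest library were chosen after seeing the data. Of 641 results of named genes 381, and of 61 calls of lists 3, kept their direction and their side of the threshold under every setting run. RLE size factors changed 1 gene result and 1 list call, thinning the deepest library 0 of 36 gene results and leaving it out 1 of 36 (TSC22D3 with docetaxel, adjusted p = 0.076), each lost and none reversed. DESeq2 lost 9 gene results and added 3, no filter on low counts lost 24 and fits of the compared groups lost 16 and added 8. Leaving out 1 replicate lost 35 to 53 gene results and 2 to 17 list calls. A prior count of 0.5 kept the direction and side of the threshold of the 3 A549 marker levels (6.43 for A549, 0.40 for AB598 and 0.65 for ATP). Not every small change was recovered at the depth and spread of these libraries: of simulated genes changed 1.5-fold, 42% were recovered for AB598 alone, 50% for AB598 with docetaxel and A549, 46% for docetaxel and 58% for ATP alone. Unless a reason is given, the cause was not tested.

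Without the donor block, which gives up the pairing of libraries by donor and so widens the error, 148 gene results and 17 list calls were lost and 0 reversed. Calls numbered 49 for AB598 with docetaxel and A549, 4690 for ATP alone and 4369 for ATP with docetaxel. They numbered 1064 for ATP with docetaxel and A549, 2 for docetaxel (TUBB and TUBB4B) and 3700 for A549. They were 0 and 452 for the interactions of AB598 and of ATP with A549 cells. Lists called without the block numbered 0, 0, 3 and 5 for AB598 alone, AB598 with docetaxel, ATP alone and docetaxel. ENTPD1 with AB598 in the co-culture was no longer called without the block (0.88), without the filter (0.85) and with the covariate (0.65). The A549 marker level with ATP (0.64) no longer passed the test (exact p = 0.359). The block moved no other count of calls by over 1.5 times.

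Few calls are named here after their values were seen. In fits of the compared groups 1 gene (SLC5A3), 2 genes (SLC5A3 and THBS1) and 1359 genes were called for AB598 alone, with docetaxel, and with docetaxel and A549. They numbered 11 for docetaxel, and 144 and 1306 for the interactions of AB598 and of ATP with A549 cells. DESeq2 called 1 (MKKS), 3 (TLR9 and 2 without a symbol) and 14 genes for AB598 alone, AB598 with docetaxel and docetaxel, with fitted log2 fold changes of at least 18.10 in AB598 comparisons. It called 221, 4 (MKKS, TLR9 and 2 without a symbol) and 3 (MKKS, F8A2 and 7SK) for the interactions of AB598 with A549 cells, of AB598 with docetaxel and of ATP with docetaxel. Without the filter on low counts, which tests more genes, 408 genes were called for AB598 with docetaxel and A549 and 35 and 1375 for the interactions of AB598 and ATP with A549 cells. Lists called then numbered 0 for AB598 alone, 2 for AB598 with docetaxel, 10 for ATP alone and 5 for docetaxel. With an estimated correlation lists called numbered 0 for AB598 alone, AB598 with docetaxel, AB598 with docetaxel and A549, ATP alone, and ATP with docetaxel and A549. They numbered 1 for ATP with docetaxel, docetaxel and A549.

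With the A549 marker level as a covariate, in fits of the compared groups, 86 of 154 gene results were lost. Then 236 genes (1359 without it) were called for AB598 and 27 (5164) for ATP in the co-culture. The interaction of AB598 with A549 cells gave 299 (144). For ATP the covariate reversed the sign of 15 named genes, none then called. Higher were PDIA3 (0.078), CXCL10 (1.53), IL10 (0.30), LPCAT3 (0.023), CLEC7A (0.35), XBP1 (0.088) and HSP90B1 (0.078). Lower were BBC3 (-0.21), AEN (-0.0035), AURKA (-0.23), TPX2 (-0.42), CYP24A1 (-0.045), AKR1B10 (-0.070) and CD8A (-0.013). KRT81 was at -0.47.

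Donors 1 to 3 only and donors 4 to 6 only, with fewer samples, each lost 90 gene results. Donors 1 to 3 gave 1268 calls for AB598 with docetaxel and A549, 4463 for ATP with docetaxel, 1429 for ATP with docetaxel and A549, and 3 for docetaxel (TUBA1B, TUBB and TUBB4B). They gave 229 and 924 for the interactions of AB598 and ATP with A549 cells, with 0 lists for AB598 with docetaxel and 5 for docetaxel. ENTPD1 with ATP in the co-culture became called (0.56). Donors 4 to 6 gave 15 calls for AB598 with docetaxel and A549, 0 for its interaction and 4155 for A549, with 0 lists for AB598 alone and 9 for ATP alone. ENTPD1 with AB598 in the co-culture was no longer called (0.84). In donors 1 to 3 STC2 (-0.080) and HLA-DRA (0.30) with ATP alone and HLA-DRA (0.26) with ATP and docetaxel reversed. HLA-DRA, not called in all 6 donors, was then called as higher (adjusted p = 0.018 and 0.047). In donors 4 to 6 CD86 with ATP in the co-culture (-0.32, not called in all 6 donors and then called as lower, adjusted p = 0.021), IL6 with A549 cells (-0.015) and 2 lists with AB598 in the co-culture reversed, dendritic cell maturation (adjusted p = 0.727) and cell cycle (adjusted p = 0.290).

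Over the fits that leave out 1 replicate, calls ranged from 147 (without replicate 3) to 637 for AB598 with docetaxel and A549 (406, 347 and 408 without replicates 1, 2 and 6). They ranged from 2375 (without replicate 4) to 3671 for ATP with docetaxel and A549 and from 3 to 8 for docetaxel (4, 4 and 3 without replicates 4, 5 and 6). TAGLN2, TUBB and TUBB4B were called in each of these 3, LMNA without replicate 4 and TCF7 without replicate 5. Calls ranged from 0 to 60 for the interaction of AB598 with A549 cells (0, 6, 0 and 7 without replicates 1, 2, 3 and 6) and from 1240 to 1763 for that of ATP (1240 and 1334 without replicates 4 and 6). Lists called ranged from 0 to 3 for AB598 alone (1, 1 and 0 without replicates 3, 5 and 6) and from 1 to 4 for AB598 with docetaxel (2 and 1 without replicates 5 and 6). They ranged from 4 to 14 for AB598 with docetaxel and A549 (7 and 4 without replicates 5 and 6) and from 5 to 8 for docetaxel (5 without replicate 2 or 6). The A549 marker level ranged from 5.13 to 5.66 for A549 and from 0.51 to 0.73 for ATP in the co-culture, higher in 5 of 5 donors each time. The cause is the number of donors, as 5 pairs cannot give an exact p under 0.0625. ENTPD1 with AB598 in the co-culture ranged from 0.73 to 0.97 and among these fits was called only without replicate 5.

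The small medians of the ATP signature with AB598 away from A549 cells lost their call with an estimated correlation (-0.060 and 0.070 with docetaxel, -0.043 and 0.076 for AB598 alone). The higher signature also lost it without the filter (-0.060 with docetaxel and -0.073 for AB598 alone), in donors 1 to 3 (-0.037 with docetaxel) and in donors 4 to 6 (-0.055 with docetaxel and -0.042 for AB598 alone). Per donor the lower signature was above 0 in 6 of 6 donors (0.079 with docetaxel and 0.094 for AB598 alone, exact p = 0.03125). The higher signature also lost its call without replicate 2 or 6, and for AB598 alone without replicate 3. For the ATP signature in AB598 comparisons, higher signature, AB598 with docetaxel gave -0.078 to -0.035 over single replicates left out, and AB598 alone -0.066 to -0.034. Both signatures kept their call with AB598 in the co-culture under every setting run.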

Other observations

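Of the tests below, that of the deepest library was chosen only after the result was seen. Some of the 29 genes that moved beyond every A549 marker with AB598 in the co-culture are named here after their values were seen. They include TRH and PTPRN (log2 fold change 7.74 ± 0.80 and 6.74 ± 0.99, adjusted p = 1.2e-07 and 8.6e-05). Others were the neuropeptide precursor gene CALCA (3.34 ± 0.53, 0.00011), the prohormone-processing gene CPE (3.14 ± 0.49, 7.9e-05), and the synaptic vesicle gene SV2C (5.39 ± 0.87, 0.00014). Further ones were the orexin receptor gene HCRTR1 (2.75 ± 0.49, 0.00051) and the sodium channel gene SCN11A (2.38 ± 0.47, 0.0014). With ATP in moDCs alone TRH, CPE, SV2C, HCRTR1 and SCN11A had log2 fold changes of 5.66, 5.66, 7.03, 4.82 and 4.04. Adding ATP to the AB598-treated co-culture gave 3.22 for PTPRN and 2.69 for SV2C (adjusted p = 3.0e-05 and 3.9e-05). It gave -0.68, 0.59, 0.88, 0.88 and 0.41 for TRH, CALCA, CPE, HCRTR1 and SCN11A, none of which was called. No list of these genes was fixed, so a shared function was not tested.

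Unplanned comparisons of docetaxel in the AB598 groups and in those with AB598 and ATP share no library with the docetaxel comparison above. Summed CPM of the alpha-tubulin genes rose in the isotype background by a mean log2 difference of 0.59 ± 0.296 (6 of 6 donors, exact p = 0.03125, adjusted p = 0.035). TUBA4A, TUBA1B, TUBB2A and TUBB6 rose by 0.95 ± 0.210, 0.70 ± 0.344, 0.67 ± 0.300 and 0.40 ± 0.190 (each in 6 of 6 donors, the same p). edgeR called none (adjusted p = 0.95 for TUBA4A and 0.0503 for TUBA1B). TUBA1A and TUBA1C did not pass (0.37 ± 0.374 and 0.41 ± 0.271, 5 of 6 donors, exact p = 0.094 and 0.0625, adjusted p = 0.094 and 0.065). TAGLN2 fell in each background (-0.81, -0.80 and -0.58, adjusted p = 0.00012, 0.00014 and 0.037). LMNA and TSC22D3 were called with AB598 (-0.79 and -1.58, adjusted p = 0.012 each) and not with AB598 and ATP (-0.35 and -1.12, adjusted p = 1 and 0.33). That difference was not tested. The number of genes called was 7, 6 and 7 in the isotype, AB598 and AB598 with ATP backgrounds.

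The rise of TUBB and TUBB4B transcripts with docetaxel was set against technical explanations. A shift of reads between near-identical tubulin genes is argued against, since the summed CPM of the beta-tubulin genes rose by a mean log2 difference of 1.02 ± 0.348 in 6 of 6 donors, from 1010.4 ± 223 to 2002 ± 111 CPM. The deep isotype library is argued against too, since at least 95.3% of the log2 fold changes remained without it. The values are consistent with docetaxel acting on tubulin mRNA. Both genes were higher with it in 6 of 6 donors in the AB598 and the AB598 with ATP backgrounds. The tubulin list was called with an estimated correlation in all 3 (adjusted p = 1.5e-08, 5.9e-09 and 1.2e-11). As the pattern was found and tested in these data it stays a hypothesis.

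Other assignments of the donors' paired libraries to the 2 arms (32 splits that part every pair, the real one included, each fitted to the compared groups) were used to ask whether chance could give as many called genes. Only the real split was as large (1 of 32, the fewest possible, unadjusted) for AB598 in the co-culture (1359 genes against at most 0 in the other splits), ATP alone (5581 against 0), ATP with docetaxel (6076 against 1), and ATP in the co-culture (5164 against 0). The same holds for docetaxel (11 against 2) and A549 (4505 against 0). For AB598 with docetaxel the real split was also the only one as large (2 against 1), but by 1 gene. No gene was called there in the fit of all libraries, so those 2 genes are not taken as an effect. Of 48 splits that did not part every pair, 3 called as many or more. For AB598 alone the count does not speak against chance (1 against 2, with 4 of 32 splits as large). Interactions were fitted here with each pair of libraries as a block, which gives other counts than a donor block. Only the real split was as large for AB598 with A549 cells (1340 against 1) and ATP with A549 cells (2567 against 0). For the interactions of AB598 with docetaxel (0 against 1) and of ATP with docetaxel (0 against 0) a real count of 0 makes 32 of 32 splits as large by construction, which says nothing about chance. Among 48 drawn splits of each comparison that did not part every pair, up to 891 genes were called (ATP in the co-culture, below its real count). Up to 58 were called for docetaxel and 79 for AB598 with docetaxel, several times the real counts, which points to a structure of the samples whose source was not tested. Among 18 such splits of each interaction at most 1 gene was called.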
